A study of Homo sapiens with 16 samples.

How the data were processed

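RNA from human antigen-specific CD8+ T cell clones was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per culture and 16 arrays in all. Each of 8 clones had been expanded in a culture with eAPC and in a culture with eAPC:4-1BBL. The labels do not expand the name eAPC. Clones 1 to 5 were sampled at day 3 and clones 6 to 8 at day 7, so day and clone set cannot be separated. According to the labels, all cultures held IL-2 at 50 cu/ml, anti-CD3 antibody at 25 ng/ml and irradiated feeder cells from blood.

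The deposited values were linear signal intensity values per probe set that the authors had computed with MAS5, whose version is not given in the sources used here. The mean over the middle of each array's distribution, without the top and bottom 2%, was 150 on all 16 arrays, so the arrays had been scaled to a common level. Median signal per array ranged from 21.3 to 31.8 and the highest signal from 18410 to 30680. Detection calls were not used here, and filters or pooling by the authors are not given. For arrays, the number of clones limits the precision: 5 pairs at day 3 and 3 pairs at day 7.

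Of 54675 probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none. Symbols of 41043 probe sets were updated through their Entrez identifiers. The 118 probe sets of XIST, TSIX and genes of the Y chromosome were dropped before any fit. Values were turned into log2(signal + 16), and the 50% of probe sets with the higher mean, 27337 probe sets, were kept. Among probe sets with 1 symbol, the brightest stood for its gene, which left 11939 tested genes out of 19728. No further normalization between arrays was applied.

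Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with 1 mean per combination of day and culture and a spread shared by all 16 arrays (12 residual degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05 and no minimum fold. The contrasts of cultures set eAPC:4-1BBL against eAPC: at day 3, at day 7, and over both days with the same weight for each of the 8 clones. Another contrast was the day 7 difference minus the day 3 difference. Day 7 was set against day 3 on the 8 clone means, 5 against 3. The clone numbers in the labels pair the arrays, and a fit with the clone as a replicate block (6 residual degrees of freedom) was run beside the unblocked one. The pairing was checked in the values. After the mean of its group was removed from each array, the correlation between the arrays of a clone was 0.267 to 0.767. Among arrays of the same day and the other culture type, 15 of 16 arrays were then closest to that of their own clone. Without that removal, the eAPC array of clone 1 and the arrays of clones 7 and 8 correlated more with another clone's array. For clone 7 with eAPC:4-1BBL the values were 0.971 with another clone and 0.961 with its own. Differences, folds and SDs between pairs are identical in both fits, while the p-values are not. Named differences are given as eAPC:4-1BBL minus eAPC unless a sentence says otherwise. Folds of genes are ratios of signal + 16, while mean signals are given without the 16. For dim genes a fold is therefore smaller than the ratio of the signals.

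Gene lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the 21 gene lists or over the 10 marker lists. Each test was repeated with an estimated correlation, with fry, with the replicate block, and by exact sign flips of the clone pairs. Smallest possible p-values of sign flips were 0.00781 for 8 pairs, 0.0625 for 5 pairs and 0.25 for 3 pairs, so day 3 or day 7 alone could not pass. The gene lists were 4-1BB and NF-kB response, costimulatory receptors, inhibitory receptors and exhaustion, naive and memory, cytotoxic effector, cytokines and chemokines, cytokine receptors and STAT response, chemokine receptors and adhesion, early activation, cell cycle, glycolysis, hypoxia response, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, interferon response, apoptosis promoting, apoptosis opposing, unfolded protein and amino acid stress, heat shock, and cytosolic ribosomal proteins. The marker lists were CD8 T cell, CD4 and regulatory T cell, NK cell, B cell or lymphoblastoid line, monocyte or macrophage or dendritic cell, erythroid or erythroleukaemia line, platelet or megakaryocyte, fibroblast, melanoma or melanocyte, and epithelial. The erythroid score of an array is the mean log2 value of the measured members of the erythroid list.

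Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For each contrast of cultures, the rule named the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold without a block and changed the same way in every pair. For each list it named up to 2 members that rose most and up to 2 that fell most in either fit, over all genes or over the list alone, or 1 member as a value where none passed. For the comparison of days it named the 10 largest changes in each direction among genes past the threshold and without overlap between the clones of the days. TNFSF9, TNFRSF9, CD28, IL2RA, IFNG, GZMB, PRF1, CCR7, IL7R, BCL2L1 and MKI67 were always named. TCF7 was on that list as well but had no probe set with a single symbol, so it was not analysed here. HLA genes and variable segments of receptor genes were never named. CD5, CD8B, CD247, JCHAIN, BANK1 and POU2AF1 in the closing section, and HBE1, were named after their values had been seen.

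Alternatives covered pseudocounts of 1 and 64, no filter and a filter to the brightest 30%, quantile normalization, array medians set equal, a mean over probe sets, eBayes without trend and robust eBayes, array weights, the arrays of a single day, each clone left out, and the clone as a random effect (correlation 0.532). For lists with the random effect, which camera does not take, the pre-ranked form of camera was used. An erythroid score as a covariate, the test of lists on the day 7 difference minus the day 3 difference, the marker lists at day 3 and between the days, the agreement between the days and the splits that part every clone pair were added after the data had been seen. Correlations between the days were taken across genes, with the sign patterns of the 8 pairs as the reference. Measures of array quality were compared with exact permutation tests, 6 in a family. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

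The gene tests were tested on simulated data of the same design and size, in which 200 of 11939 genes changed by a log2 difference of 0.5, 1 or 2. At day 3, 22.4%, 55.2% and 95.5% of changed genes were recovered without a block and 43.3%, 76.1% and 100% with it. At day 7 the shares were 1.49%, 50.7% and 83.3%, and 11.9%, 67.2% and 95.5% with the block. Over both days they were 29.9%, 82.1% and 97.0%, and 47.8%, 91.0% and 100% with the block. For day 7 against day 3 they were 10.4%, 56.7% and 93.9%. False calls made up 0% (day 3), 0% (day 7), 0.714% (both days) and 6.14% (days) of calls without a block, and 3.95%, 3.33% and 1.85% of calls with it. The simulated genes varied independently of each other, without the correlation between genes or the sample structure of the real arrays. The rates of false calls therefore need not hold for the real data.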

Results

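Expression was measured in 16 cultures of 8 human CD8+ T cell clones, each clone expanded once with eAPC and once with eAPC:4-1BBL, that is, with the ligand of the costimulatory receptor 4-1BB. Day 3 held 5 clones per culture type and day 7 held 3 other clones per culture type. The question was which genes differ between the culture types. Median signal per array ranged from 21.3 to 31.8, and the 3'/5' signal ratio ranged from 1.05 to 1.15 for ACTB and from 0.927 to 1.06 for GAPDH. Pairs of arrays correlated at 0.820 to 0.978 across genes. Signal of HBE1, an embryonic haemoglobin chain, ranged from 39.3 to 9000 between arrays.

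Across all 8 clones, CCR7, the chemokine receptor that guides T cells to lymph nodes, was 13.8-fold higher with eAPC:4-1BBL (log2 difference 3.79 ± 1.05, SD of pairs, n = 8; adjusted p = 0.000603). HILPDA, a lipid droplet protein induced by low oxygen, rose 10.7-fold (3.42 ± 1.74, adjusted p = 0.000209), and ADM, the peptide adrenomedullin, rose 6.97-fold (2.80 ± 1.91, adjusted p = 0.0150). EBI3, a cytokine subunit, rose 4.51-fold (2.17 ± 0.57, adjusted p = 0.00203), and FCER2, a low-affinity IgE receptor, rose 3.76-fold (1.91 ± 0.81, adjusted p = 0.0159). SAMHD1, an enzyme that breaks down deoxynucleotides, fell 2.47-fold (-1.31 ± 0.26, adjusted p = 3.92e-06). The chemokine receptors CCR1 and CXCR6 fell 2.71-fold (-1.44 ± 0.58, adjusted p = 0.0400) and 2.57-fold (-1.36 ± 0.34, adjusted p = 0.0436). Each of these genes changed the same way in 8 of 8 pairs, which the naming rule required. Here and in the paragraphs below, SDs of differences are of pairs. Adjusted p-values of limma and camera that are not given as blocked are from the fit without a block. The error of that fit includes the spread between clones, so those p-values do not measure the spread of pairs.

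Further genes that rose in all 8 pairs were ANKRD37 (4.38-fold), HSPA6 (4.19-fold), an inducible heat shock protein, RGS16 (4.06-fold), a regulator of G protein signalling, CRTAM (3.73-fold), an adhesion receptor of activated T cells, and PFKFB4 (3.50-fold), an enzyme that regulates glycolysis. Further genes that fell in all 8 pairs were NFKBIZ (2.84-fold), a nuclear regulator of NF-kB, the interferon-inducible DDX60 (2.63-fold), CRIM1 (2.58-fold), ZBP1 (2.49-fold), a sensor of nucleic acids, C3AR1 (2.38-fold), a complement receptor, SLFN5 (2.36-fold) and AGTRAP (2.25-fold). The plot of single clones shows 8 of the genes with the largest changes.

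**Figure D1:**
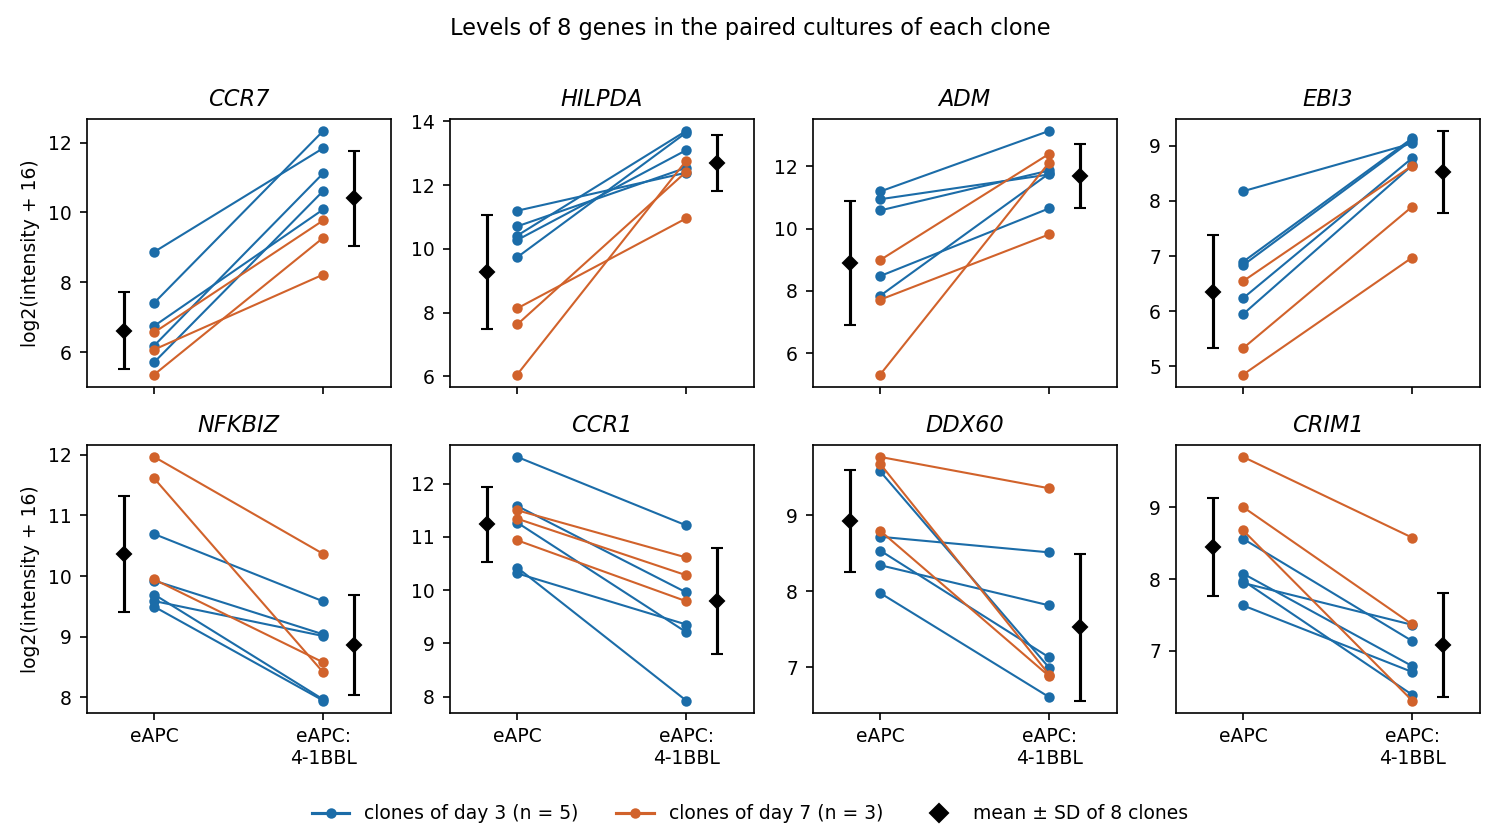
Log2(intensity + 16) of 8 genes in the eAPC and the eAPC:4-1BBL culture of each clone (blue, day 3, n = 5; orange, day 7, n = 3; lines join the cultures of a clone; black diamonds, mean ± SD of 8 clones). CCR7, HILPDA, ADM and EBI3 were higher and NFKBIZ, CCR1, DDX60 and CRIM1 lower with eAPC:4-1BBL in 8 of 8 pairs, as the naming rule required. Mean log2 differences ran from 3.79 for CCR7 to -1.50 for NFKBIZ.

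Without a block, limma called 883 of 11939 genes over both days, 515 higher and 368 lower. With the replicate block it called 3207, 1678 higher and 1529 lower, and these included all 883. With array medians set equal, the median of all genes moved from -0.01 to 0.10 (0.12 at day 3) the unblocked calls to 672 higher and 76 lower, and the blocked calls to 2533 higher and 643 lower, so the changes are relative to the scaling of the deposited values. CCR1, CXCR6 and DDX60 did not pass with medians set equal. In the blocked fit all 20 genes with the largest changes, picked as changed alike in all 8 pairs, stayed past the threshold without each clone in turn. Without a block 10 of them did, and the count fell to 299 without clone 7, 362 without clone 5, 381 without clone 8 and 573 without clone 1.

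Among the always-named genes, TNFRSF9, which encodes 4-1BB itself, was 2.74-fold higher (1.45 ± 0.47, 8 of 8 pairs), past the threshold only in the blocked fit (adjusted p = 0.0503 without and 0.000122 with the block). TNFSF9, the gene of 4-1BBL, was 1.66-fold higher (0.73 ± 0.37; blocked adjusted p = 0.000909), and IL2RA, the alpha chain of the IL-2 receptor, 1.34-fold higher (0.42 ± 0.28; blocked adjusted p = 0.00360). Each was higher in 8 of 8 pairs. Whether the TNFSF9 RNA came from the T cells or from other cells in the eAPC:4-1BBL cultures was not tested. Also past in the blocked fit only were MKI67, a proliferation marker (0.32 ± 0.28, adjusted p = 0.0192), PRF1, the pore protein perforin (-0.39 ± 0.25, adjusted p = 0.000710), GZMB, granzyme B (-0.33 ± 0.44, adjusted p = 0.0496). The same held for the costimulatory receptor CD28 (-0.55 ± 0.43, adjusted p = 0.00750) and IL7R, a survival cytokine receptor (-0.48 ± 0.42, adjusted p = 0.0290). IFNG, interferon gamma, had a log2 difference of 0.54 ± 0.89 (blocked adjusted p = 0.120) and BCL2L1, an inhibitor of apoptosis, of 0.14 ± 0.39 (blocked adjusted p = 0.443). Neither passed in either fit.

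Over both days, of 21 measured glycolysis genes 15 rose and none fell (18 and 0 adjusted over the list alone), among them PFKFB4 and ALDOC (2.27-fold, adjusted p = 0.00224). The list mean was 0.61 ± 0.37 (SD of 8 pairs; camera adjusted p = 2.48e-14, adjusted p = 0.0991 with an estimated correlation). Of 17 hypoxia response genes 7 rose and none fell (12 and 0 adjusted over the list alone), with a mean of 1.03 ± 0.63 (camera adjusted p = 5.87e-10, adjusted p = 0.160 with an estimated correlation). Oxidative phosphorylation had 6 of 29 members up (10 over the list alone), such as UQCRC2 (1.51-fold) and COX5B (1.31-fold), subunits of respiratory complexes. Its mean was 0.23 ± 0.07 (camera adjusted p = 8.57e-09, adjusted p = 0.160 with an estimated correlation). Fatty acid oxidation had 3 of 17 up, ETFB (1.45-fold) and CPT2 (1.37-fold) among them, and 6 up and 1 down adjusted over the list alone. CPT1A, which brings fatty acids into mitochondria, was the 1 that fell (-0.49 ± 0.33). Its mean was 0.18 ± 0.08 (camera adjusted p = 0.00251, adjusted p = 0.160 with an estimated correlation). Cholesterol synthesis had 8 of 18 up (11 adjusted over the list alone), with SQLE (1.95-fold), a rate-limiting enzyme, and STARD4 (1.83-fold), a cholesterol transporter. Its mean was 0.47 ± 0.20 (camera adjusted p = 3.29e-08, adjusted p = 0.160 with an estimated correlation). These 5 list means were positive in 8 of 8 pairs. The erythroid score of the same pairs differed by -0.22 ± 0.86, higher in 4 pairs and lower in 4.

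**Figure D2:**
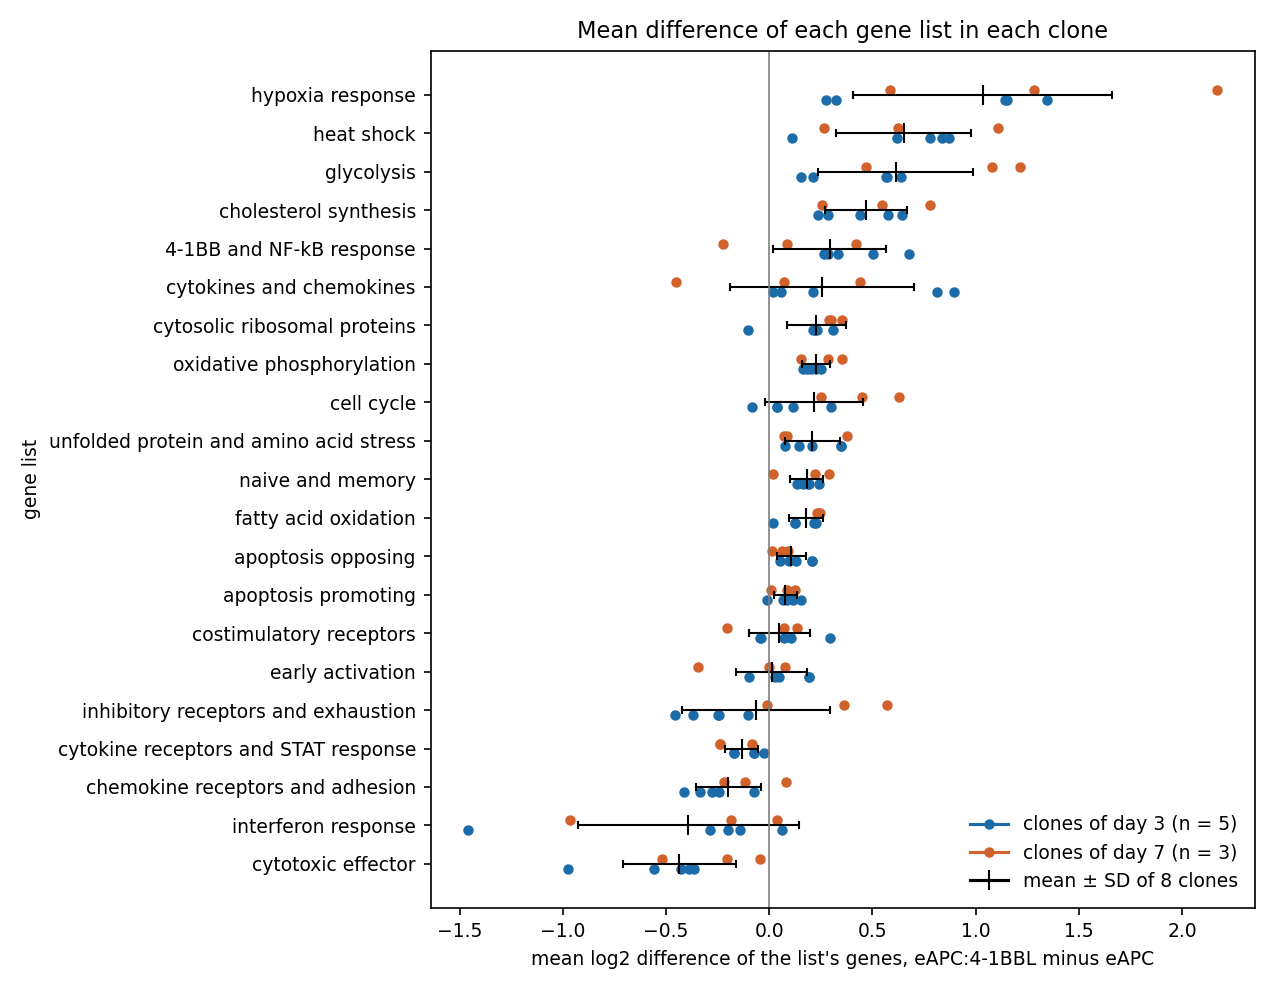
Mean log2 difference (eAPC:4-1BBL minus eAPC) of the measured members of each of 21 gene lists, 1 point per clone (blue, day 3, n = 5; orange, day 7, n = 3), with the mean ± SD of the 8 clones in black. Hypoxia response lay at 1.03 ± 0.63 and glycolysis at 0.61 ± 0.37, while cytotoxic effector lay at -0.44 ± 0.27.

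Heat shock genes (4 of 12 rose and 1 fell; 8 and 1 adjusted over the list alone) had a mean of 0.65 ± 0.33 (camera adjusted p = 0.000145, adjusted p = 0.160 with an estimated correlation). HSPA6 and the cochaperone DNAJB1 (2.24-fold) rose, and HSPA1L fell 1.73-fold. Cytosolic ribosomal protein genes had 12 of 23 up (18 adjusted over the list alone), such as RPL3 (1.43-fold) and RPL8 (log2 difference 0.49). Their mean was 0.23 ± 0.14 (camera adjusted p = 8.17e-14, adjusted p = 0.160 with an estimated correlation). It depended on the scaling: 0.11 after quantile normalization and 0.35 with array medians set equal, and oxidative phosphorylation moved to 0.15 and 0.35. With array medians set equal, fatty acid oxidation was at 0.29, unfolded protein and amino acid stress at 0.32 and cell cycle at 0.34. Unfolded protein and amino acid stress had 3 of 23 up (6 over the list alone) with a mean of 0.21 ± 0.13 (camera adjusted p = 0.00899, adjusted p = 0.160 with an estimated correlation). PHGDH, an enzyme of serine synthesis, rose 1.92-fold. In the blocked fit only, PSAT1 of the same pathway rose (1.77-fold), and CEBPB (-0.56 ± 0.22) and CRELD2 (-0.53 ± 0.27) fell. The signal of the 28S ribosomal RNA control probe set M was also higher with eAPC:4-1BBL in 8 of 8 pairs (0.46 ± 0.28; exact permutation p = 0.00781, adjusted p = 0.0469 over 6 measures), while that of the 28S probe set 5 differed by 0.13 ± 0.33 (exact permutation p = 0.289). Median signal was lower in 6 of 8 pairs (-0.12 ± 0.13; exact permutation p = 0.0469, adjusted p = 0.141).

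The 4-1BB and NF-kB response list, 23 genes, had 6 up and 1 down (8 and 2 adjusted over the list alone) and a mean of 0.29 ± 0.27 (7 of 8 pairs; camera adjusted p = 0.00150, adjusted p = 0.163 with an estimated correlation). LTA, the cytokine lymphotoxin alpha, rose 3.16-fold (1.66 ± 1.03, adjusted p = 0.0444), while NFKBIZ fell and IRF1, an interferon-regulated factor, was lower in the blocked fit only (-0.55 ± 0.36). Cell cycle genes had 1 of 35 up, the mitotic kinase BUB1 (1.53-fold, adjusted p = 0.0464), and none over the list alone. With the block 17 rose and 1 fell (20 and 1 over the list alone). The 1 that fell was CCNE2, a cyclin (-0.50 ± 0.34), and CDT1, a replication licensing factor, passed over the list alone in the blocked fit (0.56 ± 0.77). The mean of cell cycle genes was 0.22 ± 0.24 (7 of 8 pairs; camera adjusted p = 0.00809, adjusted p = 0.666 with an estimated correlation).

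Cytotoxic effector genes had no member past the threshold without a block, over all genes or over the list alone, and 1 up and 13 down of 17 with it. Granzyme GZMH (1.94-fold lower, -0.96 ± 0.56; blocked adjusted p = 0.000917) and the NK receptor chain KLRD1 (2.06-fold lower, -1.04 ± 0.49; blocked adjusted p = 0.000887) were among them. The 1 that rose was the transcription factor ZEB2 (0.53 ± 0.49). The list mean was -0.44 ± 0.27, negative in 8 of 8 pairs (camera adjusted p = 0.00456, adjusted p = 0.379 with an estimated correlation). Interferon response had 1 of 27 down (1 over the list alone), PARP9 (1.89-fold, adjusted p = 0.0139), and 11 down with the block, CMPK2 (-0.89 ± 1.02) among them. SAMD9 was past only over the list alone with the block, and in the other direction (0.44 ± 0.56). The list mean was -0.39 ± 0.54, lower in 6 of 8 pairs (camera adjusted p = 0.00101, adjusted p = 0.379 with an estimated correlation), and -0.24 without clone 4. Chemokine receptors and adhesion had 3 of 19 down (4 over the list alone) and of the fits as deposited passed only in the blocked one (-0.20 ± 0.16; camera adjusted p = 0.0582, blocked 0.0145, blocked adjusted p = 0.192 with an estimated correlation). Its mean was -0.0817 with array medians set equal. VCAM1 (1.28 ± 0.73) and CCR8 (1.23 ± 1.10) of that list were higher in the blocked fit only.

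The other gene lists did not pass camera over both days. Costimulatory receptors (1 up and 2 down of 16; 2 and 3 over the list alone) held CRTAM, which rose, and SLAMF1 (1.64-fold) and CD6 (1.63-fold), which fell. The list's mean of 0.05 was positive while its median of -0.24 and the test pointed down (adjusted p = 0.423). Naive and memory (1 up of 17, CCR7, and 1 over the list alone) had a mean of 0.18 and a median of -0.03 (adjusted p = 0.721). In the blocked fit only, MYB was higher (0.88 ± 1.03) and CD27 lower (-0.62 ± 0.51). Inhibitory receptors and exhaustion (0 of 16 in limma, 3 up and 4 down with the block) had a mean of -0.06 (adjusted p = 0.859). That mean joins opposite values, -0.29 at day 3 and 0.31 at day 7. In the blocked fit CD200 (0.83 ± 0.89) and ENTPD1 (0.49 ± 0.86) were higher and EOMES (-0.95 ± 0.31) and CTLA4 (-0.77 ± 1.20) lower. Cytokines and chemokines (1 up of 15, LTA, and 1 over the list alone) had a mean of 0.26 (adjusted p = 0.478). XCL1 was higher (1.89 ± 2.70) and CCL4 lower (-1.03 ± 0.94) in the blocked fit only, and IL10 was lower (-0.55 ± 0.59) over the list alone with the block. IL10 was dim outside clone 3. Its log2 values were 10.49 and 8.87 in clone 3, 4.74 to 5.80 in the other day 3 clones, and 4.81 on average at day 7. Cytokine receptors and STAT response (1 up and 2 down of 22; 3 and 2 over the list alone) had a mean of -0.13 (adjusted p = 0.340), with IL21R up 2.89-fold and IL18R1 down 1.84-fold. SOCS2 (0.43 ± 0.38) and IL18RAP (-0.99 ± 0.66) passed in the blocked fit only. Early activation (3 up and 1 down of 19; 5 and 2 over the list alone) had a mean of 0.01 and a median of -0.04 (adjusted p = 0.423), with IER3 up 2.48-fold. IRF4 (2.01-fold higher), EGR1 (-1.22 ± 0.53) and CD69 (-1.16 ± 0.50) passed in the blocked fit only.

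Apoptosis genes moved both ways. Of 16 genes that promote it 1 rose, PMAIP1 (2.34-fold, adjusted p = 0.00220), and over the list alone 3 rose and 1 fell. The list mean was 0.08 and its median -0.07 (camera adjusted p = 0.726). BCL2L11 (-1.05 ± 0.44), which encodes BIM, and BMF (-0.45 ± 0.34) were lower and BNIP3, also a hypoxia response gene, higher (1.34 ± 1.19) in the blocked fit only. Of 13 genes that oppose it 2 rose and 1 fell (2 and 1 over the list alone), with a mean of 0.11 (camera adjusted p = 0.563). TNFAIP3, an inhibitor of NF-kB signalling, rose 2.11-fold (adjusted p = 0.00203), CFLAR, an inhibitor of caspase activation, rose 1.56-fold (adjusted p = 0.0168), and XIAP, a caspase inhibitor, fell 1.48-fold (adjusted p = 0.00609). The CFLAR difference was 0.64 for the brightest probe set and -0.02 for the mean over its probe sets, and PIM1, a kinase, was lower in the blocked fit only (-0.38 ± 0.41). By exact sign flips of the pairs, 17 of the 21 list means differed from 0 after adjustment, a test that does not set the list against other genes.

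Of the marker lists, the CD8 T cell list was the 1 past camera over both days (1 of 12 down, 2 over the list alone, mean -0.30 ± 0.19, lower in 8 of 8 pairs; adjusted p = 0.0117, adjusted p = 0.974 with an estimated correlation). CD8A, the alpha chain of CD8, fell 1.71-fold (adjusted p = 0.00631), and CD7 was lower in the blocked fit only (-0.64 ± 0.56). With array medians set equal the list mean was -0.18, and with the mean over probe sets 0 marker lists passed camera. The list's members CD2 and CD5 also stood in the costimulatory list. List means were 0.15 for CD4 and regulatory T cell, 0.23 for B cell or lymphoblastoid line, -0.11 for monocyte, macrophage or dendritic cell, -0.22 for erythroid, -0.07 for platelet and -0.08 for fibroblast (adjusted p = 0.913 each). The NK cell list had a mean of 0.10, a median of -0.25 and a test pointing down (adjusted p = 0.913). Melanoma or melanocyte, of which MITF alone was measured, had a mean of 0.11 and epithelial of 0.02 (adjusted p = 0.945 each). Members of these lists past the threshold in the blocked fit only were CCR4 (0.73 ± 0.64), SH2D1B (0.72 ± 0.46), NCAM1 (-0.48 ± 0.33), TYROBP (-0.43 ± 0.19), AIF1 (0.84 ± 0.34) and IGHM (1.01 ± 1.78). Past over the list alone with the block were CD79B (-0.32 ± 0.23) and LYZ (-0.74 ± 1.04). TAL1 (-0.50 ± 0.99), GP9 (0.40 ± 0.45), FN1 (-0.29 ± 1.17) and ELF3 (0.16 ± 0.64) did not pass.

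At day 3, in 5 clones, CCR7 rose 18.5-fold with eAPC:4-1BBL (log2 difference 4.21 ± 0.98, SD of pairs, n = 5, adjusted p = 0.00773), from a mean signal of 111 to 2335. HILPDA rose 6.10-fold (2.61 ± 1.09, adjusted p = 0.0129), EBI3 4.35-fold (2.12 ± 0.73, adjusted p = 0.0264), ANKRD37 4.23-fold (2.08 ± 0.97, adjusted p = 0.00864) and IL21R, the receptor of a cytokine of T helper cells, 3.34-fold (1.74 ± 0.74, adjusted p = 0.00864). SAMHD1 fell 2.43-fold (-1.28 ± 0.26, adjusted p = 0.000141) and TXNIP, a brake on glucose uptake, 2.59-fold (-1.37 ± 0.54, adjusted p = 0.0101). CD8A fell as well, from a mean signal of 9770 to 4881 (SD of pairs 0.34, adjusted p = 0.0214). It fell in 5 of 5 pairs, as the naming rule required. BEND5, LDLRAD4, LINC01588, NEK6 and HSD11B1, an enzyme that makes cortisol from cortisone, rose 3.36-fold to 2.68-fold. ANTXR2, PRDM11, TMEM229B, SLC27A3, DAPK2, ATP8B2 and PTOV1-AS2 fell 2.52-fold to 1.90-fold.

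Among the lists at day 3, 4-1BB and NF-kB response had 2 of 23 up (10 up and 2 down adjusted over the list alone), TNFAIP3 (2.26-fold, adjusted p = 0.0184) 1 of them. Its mean was 0.41 ± 0.17 (5 of 5 pairs; camera adjusted p = 2.48e-05, adjusted p = 0.190 with an estimated correlation). Hypoxia response had 2 of 17 up (6 over the list alone, mean 0.85 ± 0.51) and glycolysis 1 of 21 (7 over the list alone, mean 0.43 ± 0.23), with camera adjusted p = 7.21e-08 and 6.08e-08. For both, adjusted p = 0.190 with an estimated correlation. Cytotoxic effector genes had 0 of 17 past the threshold without a block (0 over the list alone) and 11 down with it, GZMH (-1.12 ± 0.62) and PRF1 (-0.54 ± 0.17) among them. Their mean was -0.54 ± 0.25 (0 of 5 pairs higher; camera adjusted p = 0.000727, adjusted p = 0.231 with an estimated correlation). The CD8 T cell markers had 1 of 12 down (3 over the list alone; 7 with the block) and a mean of -0.42 ± 0.12 (0 of 5 pairs higher; camera adjusted p = 0.000292, adjusted p = 0.913 with an estimated correlation). Higher as well were oxidative phosphorylation (0.21), cholesterol synthesis (0.43), fatty acid oxidation (0.14), heat shock (0.64), unfolded protein and amino acid stress (0.23) and ribosomal proteins (0.17). Lower were interferon response (-0.41) and chemokine receptors and adhesion (-0.27). For these 8 lists adjusted p = 0.190 to 0.329 with an estimated correlation. After quantile normalization ribosomal proteins were at 0.0773 and oxidative phosphorylation at 0.14. With array medians set equal these were at 0.33 and 0.36, fatty acid oxidation at 0.29, unfolded protein and amino acid stress at 0.37, chemokine receptors and adhesion at -0.12 and the CD8 T cell markers at -0.27. Without clone 4 the interferon response mean was -0.14 and did not pass, and without clone 1 fatty acid oxidation did not pass. In all, 12 of 21 gene lists passed camera and 0 passed with an estimated correlation, where the lowest adjusted p was 0.190. With the replicate block 13 passed camera, and 0 with an estimated correlation as well (lowest adjusted p = 0.244). Inhibitory receptors and exhaustion, not among the 12, had a mean of -0.29, with 1 up and 6 down of 16 in the blocked fit.

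The day 3 test called 106 genes without a block, 69 higher and 37 lower, and 1791 with it, 947 higher and 844 lower. With array medians set equal the splits were 121 higher and 5 lower, and 1825 higher and 331 lower with the block, and 3 of the 10 genes named above as lower still passed without it. The unblocked count was 1 without clone 5, 2 without clone 4, 21 without clone 1, 32 without clone 3, 43 without clone 7 and 57 without clone 8. The blocked count was 861 without clone 5, 959 without clone 3 and 1032 without clone 4. All 20 genes named for day 3, picked as changed alike in every pair, kept their blocked call without each clone.

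At day 7, in 3 clones, HILPDA rose 27.4-fold with eAPC:4-1BBL (log2 difference 4.78 ± 1.94, SD of pairs, n = 3, adjusted p = 0.00165), from a mean signal of 139 to 4229. PFKFB4 rose 6.26-fold (2.65 ± 1.47, adjusted p = 0.0323), ANKRD37 4.65-fold (2.22 ± 1.05, adjusted p = 0.0208), and GPI, a glycolytic enzyme, 3.62-fold (1.86 ± 0.86, adjusted p = 0.0192). ARG2, a mitochondrial arginase, rose 3.40-fold, DUSP4, a phosphatase of MAP kinases, 3.40-fold, and AK4, a mitochondrial adenylate kinase, 3.32-fold. SAMHD1 fell 2.55-fold (-1.35 ± 0.32, adjusted p = 0.00165) and TNFSF8, the ligand of the receptor CD30, 3.24-fold (-1.70 ± 0.42, adjusted p = 0.0371). EFCAB3, SLC43A3 and CYP26A1, which degrades retinoic acid, rose 4.35-fold to 3.38-fold, and AGTRAP, PREX1, ERVK13-1, ATP8B2, LASP1NB, KLHL42, SYMPK and ARHGAP4 fell 2.80-fold to 2.02-fold. CCR7 was higher by a log2 difference of 3.09 ± 0.89, past the threshold with the block only (adjusted p = 0.0585 without and 0.00316 with it).

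Of 21 glycolysis genes at day 7, 9 rose and none fell (18 over the list alone), with a mean of 0.92 ± 0.40 (3 of 3 pairs; camera adjusted p = 6.77e-20, adjusted p = 0.0316 with an estimated correlation and 0.243 with the block and an estimated correlation). Hypoxia response had 3 of 17 up (6 over the list alone, mean 1.35 ± 0.79; camera adjusted p = 5.54e-10, adjusted p = 0.202 with an estimated correlation). Cell cycle genes had 0 of 35 past the threshold without a block (1 over the list alone) and 17 up with it, and a mean of 0.44 ± 0.19 (camera adjusted p = 4.82e-05, adjusted p = 0.624 with an estimated correlation). BUB1 was higher in the blocked fit only (1.19 ± 0.38; adjusted p = 0.0727 without and 0.00327 with the block). Ribosomal proteins had 3 of 23 up (16 over the list alone), RPL3 and RPL8 among them, and a mean of 0.32 ± 0.03 (camera adjusted p = 2.84e-16, adjusted p = 0.202 with an estimated correlation). Higher as well were oxidative phosphorylation (0.26), fatty acid oxidation (0.24), cholesterol synthesis (0.53) and heat shock (0.67), and lower was interferon response (-0.37), so that 9 of 21 lists passed camera (11 with the replicate block). For these 5 lists adjusted p = 0.202 to 0.675 with an estimated correlation. Without clone 8 the interferon response mean was -0.0745 and did not pass, nor did it with the stricter filter. Heat shock was at 0.44 without clone 7. After quantile normalization the mean of ribosomal proteins was 0.16 and that of oxidative phosphorylation 0.17. With an estimated correlation glycolysis was the 1 that passed. With the block and an estimated correlation 0 passed. The mean of 4-1BB and NF-kB response was 0.09 ± 0.32 (camera adjusted p = 0.322). Inhibitory receptors and exhaustion and cytotoxic effector were not among the 9 lists. Their means were 0.31 (4 up and 1 down of 16 in the blocked fit) and -0.26 (0 up and 4 down of 17).

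The day 7 test called 93 genes without a block, 70 higher and 23 lower, and 1405 with it, 823 higher and 582 lower. With array medians set equal the splits were 28 higher and 4 lower, and 932 higher and 267 lower with the block. The unblocked count was 0 in limma without clone 7, without clone 8 or with the arrays of day 7 alone. It was 15 without clone 5, 41 without clone 1 and 48 without clone 3. The blocked count was 0 without clone 7 and 300 without clone 8.

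The direct test of the day 7 difference against the day 3 difference called 0 of 11939 genes in limma without a block (350 genes at an unadjusted p under 0.05) and 1 with it (1301 at an unadjusted p under 0.05). That 1 was ENTPD1, which encodes the ectonucleotidase CD39, with a log2 difference of -0.11 ± 0.33 at day 3 and 1.48 ± 0.13 at day 7 (difference 1.59, SE 0.18; blocked adjusted p = 0.0200). The blocked count was 0 without clone 1, 5, 7 or 8, 2 without clone 3 and 113 without clone 6. Across 11939 genes, which are not independent replicates, the differences of the days correlated with r = 0.557 and rho = 0.529, and 69.2% had the same sign. Of 64 sign patterns of the pairs, 1 gave an r as large, and the highest other was 0.530. Unblocked calls shared by the days were 16 higher (0.405 by chance) and 6 lower (0.0713 by chance) with 0 opposite. Blocked calls shared were 393 higher (65.3 by chance) and 280 lower (41.1 by chance) with 5 opposite. The chance values assume independent calls, although the days share an estimate of the spread of each gene, so they may be too low.

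**Figure D3:**
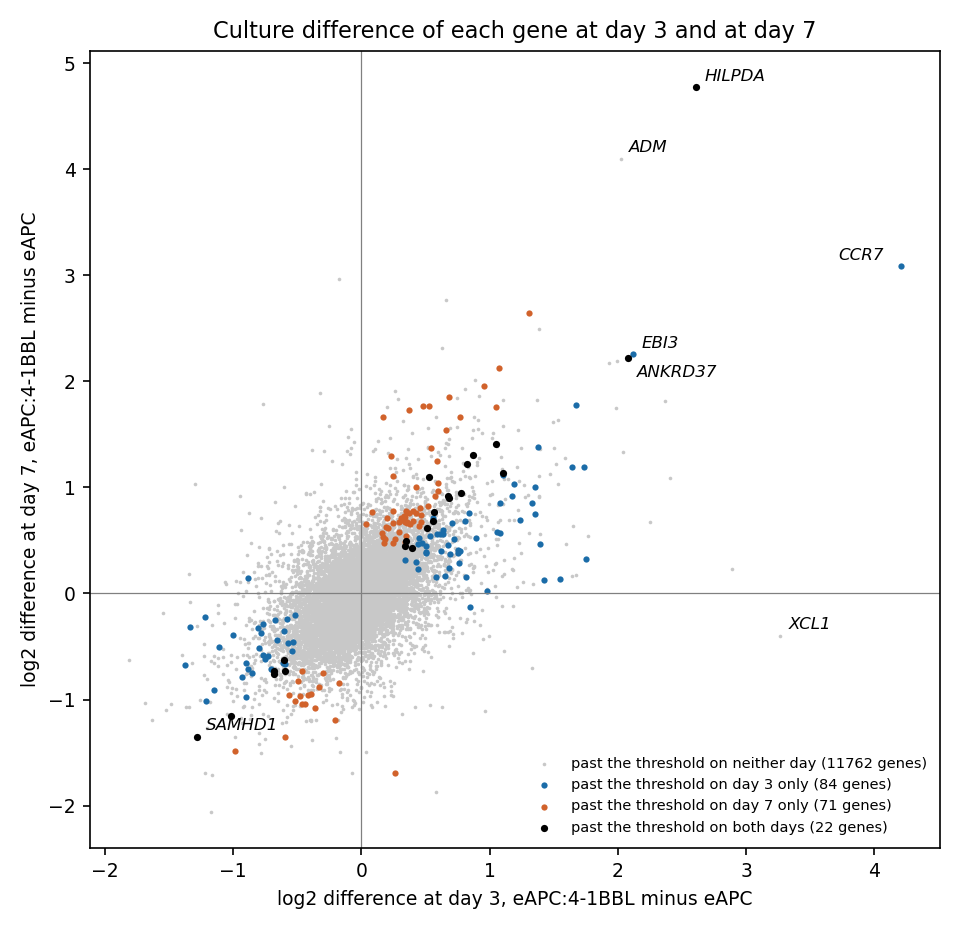
Log2 difference between the cultures (eAPC:4-1BBL minus eAPC) at day 7 against day 3 for each of 11939 genes, coloured by the unblocked call (both days, day 3 alone, day 7 alone, neither). The differences correlated at r = 0.557 across genes, and 16 genes were called higher and 6 lower on both days.

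Day 7 set against day 3 compares 3 clones with 5 others. RNASE6, an antimicrobial ribonuclease, was 6.65-fold higher at day 7 (2.73, SE 0.51; adjusted p = 0.0164), ADA2, an adenosine deaminase, 5.09-fold (2.35, SE 0.35; adjusted p = 0.0107), SLFN5 4.62-fold (2.21, SE 0.32; adjusted p = 0.0104) and PIK3IP1, an inhibitor of phosphoinositide kinase signalling, 4.23-fold (2.08, SE 0.18; adjusted p = 0.00494). RAB37, ZBP1, TC2N, GIMAP7, RIPOR2 and the sorting receptor SORL1 were 5.10-fold to 4.17-fold higher. The interferon-induced chemokines CXCL10 and CXCL9 were 13.5-fold (-3.76, SE 0.90; adjusted p = 0.0296) and 11.3-fold lower (-3.50, SE 0.87; adjusted p = 0.0333), and PFKFB4 was 4.34-fold lower (-2.12, SE 0.28; adjusted p = 0.00893). MDK, LSR, G0S2, SLC25A37, which imports iron into mitochondria, HSPB1, the complement factor C3 and the actin-bundling FSCN1 were 5.79-fold to 4.35-fold lower. MKI67 was 3.41-fold lower (-1.77, SE 0.26; adjusted p = 0.0107).

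Cell cycle genes were lower at day 7: 25 of 35 fell and none rose (33 and 0 over the list alone), with a mean of -1.23 (camera adjusted p = 1.77e-12, adjusted p = 0.473 with an estimated correlation). Glycolysis (12 of 21 down, 17 over the list alone, mean -0.67, camera adjusted p = 7.02e-08, adjusted p = 0.432 with an estimated correlation) and oxidative phosphorylation (13 of 29 down, 15 over the list alone, mean -0.39, camera adjusted p = 4.51e-06, adjusted p = 0.473 with an estimated correlation) fell as well. So did hypoxia response (5 of 17, 5 over the list alone, mean -0.71), heat shock (4 of 12, 5 down and 1 up over the list alone, mean -0.68) and ribosomal proteins (11 of 23, 18 over the list alone, mean -0.25). Cytotoxic effector genes (2 of 17 up, 2 over the list alone, mean 0.62) and chemokine receptors and adhesion (3 up and 1 down of 19, 5 and 1 over the list alone, mean 0.49) were higher. For these 5 lists adjusted p = 0.473 to 0.521 with an estimated correlation. The ribosomal mean was -0.0164 with the test pointing up after quantile normalization, and -0.0631 with array medians set equal, where oxidative phosphorylation was at -0.21 and the CD8 T cell markers at 0.39. Among the marker lists, CD8 T cell was higher (4 of 12, 6 up and 1 down over the list alone, mean 0.21, camera adjusted p = 0.0200). Erythroid was lower (0 of 17, 0 over the list alone, mean -1.91, camera adjusted p = 0.00114) and epithelial lower (0 of 6, 5 over the list alone, mean -1.75, camera adjusted p = 0.0293). With an estimated correlation adjusted p = 0.547 for each of the 3.

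The test of days called 1765 genes, 744 higher and 1021 lower, while with array medians set equal it called 884 higher and 332 lower. The clones of the days did not overlap for 1255 genes that were higher and 1652 that were lower at day 7, 24.3% of genes, where chance gives 3.57%. The erythroid score was 3.77-fold higher at day 3 than at day 7 (exact permutation p = 0.107, adjusted p = 0.161 over 6 measures), and the signal of the 28S probe set 5 was 2.64-fold higher (exact permutation p = 0.0179, adjusted p = 0.107). That p of 0.0179 is the smallest that 56 assignments can give, and a single measure there could not pass after adjustment over 6. Signals of the 28S probe set 5 did not overlap: 4985 to 10171 at day 3 and 2277 to 3563 at day 7. The 28S probe set M, which differed between the culture types, was 1.09-fold higher at day 3 (exact permutation p = 0.446). With the erythroid score as a covariate, an alternative chosen after the data had been seen, 27 genes passed. Among the 20 genes that the rule named for the days they were SLFN5 (1.44) and PIK3IP1 (1.88), with adjusted p = 0.0399 each. Of those that did not pass, PFKFB4 was at -1.91, ADA2 at 1.70 and SORL1 at 1.59, while CXCL10 was at -1.53, CXCL9 at -1.58, MDK at -0.69 and SLC25A37 at -0.59. Cell cycle (-0.89), glycolysis (-0.72), hypoxia response (-0.72), oxidative phosphorylation (-0.41) ribosomal proteins (-0.27) and unfolded protein and amino acid stress (-0.39) passed camera with the covariate. Cytotoxic effector (0.30, adjusted p = 0.365), chemokine receptors and adhesion (0.11, adjusted p = 0.295) and heat shock (-0.36, adjusted p = 0.0924) did not. The count was 1 without clone 8, 74 without clone 7, 452 without clone 5 and 638 without clone 1, and day and clone set cannot be told apart.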

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

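The tests of carried-over erythroid cells, of the share of T cells and of lists in the difference between the days were chosen after the result was seen, and the test against matched random lists and the splits of arrays were chosen before.

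Hypoxia response and glycolysis genes were higher with eAPC:4-1BBL in 8 of 8 clones, with a joint mean of 0.80 ± 0.48, while erythroid markers such as HBE1 varied widely between arrays. Carried-over erythroid cells are argued against as the whole cause: at an erythroid difference of 0 the joint mean was 0.84 (95% interval 0.41 to 1.28). The erythroid difference averaged -0.22 ± 0.86, so only a steep slope could have moved the joint mean far. The slope was 0.18 (SE 0.21). Signal distribution is argued against as well, because after quantile normalization the joint mean of 0.75 lay at percentile 100 of 10000 random lists matched on signal, whose mean was 0.00328. Differences between the eAPC lines themselves or in culture density and oxygen were not tested and stay open.

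T cell markers were lower with eAPC:4-1BBL at day 3, by a mean of -0.42 ± 0.12 in 5 pairs, and by -0.27 with array medians set equal. At an erythroid difference of 0 the mean was -0.42 (95% interval -0.62 to -0.22). The erythroid difference averaged -0.06 ± 0.95 at day 3, so only a steep slope could have moved that mean. The slope was 0.03 (SE 0.07). With that slope and no mean rise of the erythroid score, carried-over erythroid cells are argued against as the whole cause. A lower share of T cells would lower all 12 members alike, but members differed (permutation p = 1e-04, the smallest possible with 10000 permutations). CD8B differed by -0.68 ± 0.23 and CD247 by -0.19 ± 0.13, while CD5 differed by 0.16 ± 0.41 and was lower in 1 of 5 pairs. A partial change in share, and probe sets that compress large differences, stay open.

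Between the days, the difference of cultures (day 7 minus day 3) was -0.32 for 4-1BB and NF-kB response (camera adjusted p = 0.00439), 0.59 for inhibitory receptors and exhaustion (adjusted p = 0.00536), 0.36 for cell cycle (adjusted p = 0.000164) and 0.49 for glycolysis (adjusted p = 1.75e-11). It was 0.50 for hypoxia response (adjusted p = 0.0186), 0.14 for ribosomal proteins (adjusted p = 1.36e-05) and 0.31 for CD8 T cell markers (adjusted p = 0.0109). With an estimated correlation none of these lists passed, the lowest adjusted p being 0.196 for gene lists and 0.891 for marker lists. Chance cannot be excluded for the gene lists, since 65 of 100 splits called at least the 6 gene lists and the highest other split called 15. Splits were not run for marker lists on this difference, nor for the 8 gene lists that camera called with the block. ENTPD1 differed by 1.59 (SE 0.18; blocked adjusted p = 0.0200), and chance cannot be excluded here either, since 4 of 56 assignments of clones to days called at least 1 gene, up to 7. Without clone 1, 5, 7 or 8 no gene passed that blocked test, and without clone 6 the count was 113. For the unblocked count of 0 genes in limma (350 at an unadjusted p under 0.05) 100 of 100 splits reach as many by construction, so they tell nothing, and the highest other called 72.

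Single cultures stood apart by the Dixon test in 15 of 352 groups, where chance flags about 1 in 20 groups, here 17.6, and 9 of the 15 were cultures of clone 3. Groups of 3 were not tested, so only day 3 cultures entered, and values are log2 with the range of the other 4 clones in brackets. In the eAPC culture of clone 3, IL10 was at 10.49 (4.74 to 5.80), CMPK2 at 7.34 (9.20 to 9.76), NEK6 at 6.04 (6.64 to 6.79), RPL8 at 12.90 (13.17 to 13.27) and the costimulatory list at 8.99 (8.46 to 8.56). In the eAPC:4-1BBL culture of clone 3, IL10 was at 8.87 (4.82 to 5.07), LTA at 8.73 (10.74 to 11.22), IER3 at 8.90 (10.11 to 10.40) and STARD4 at 9.40 (10.42 to 10.79). In clone 4, BNIP3 with eAPC was at 6.98 (9.02 to 9.81), CDT1 with eAPC:4-1BBL at 8.38 (8.93 to 9.12) and the interferon list with eAPC at 9.20 (7.98 to 8.08). In clone 2, AIF1 with eAPC:4-1BBL was at 8.25 (10.01 to 10.66), the cytotoxic list with eAPC at 9.53 (10.33 to 10.66) and the NK cell list with eAPC at 6.97 (7.50 to 7.67). Without clone 3 the day 3 count was 32 instead of 106, without clone 4 it was 2 and without clone 2 it was 129.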

How the results depend on the processing

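Signal over background limits what dim genes can show: signal below background was not separated from low expression, and the pseudocount compresses their differences. Saturation of bright probe sets was not tested. Of the values compared with the first choice of settings, 183 of the counts stayed within 1.5 times and 70 moved beyond it. Of single-gene values 2585 kept their call, 121 gained one, 480 lost one and 5 reversed sign. Of list values 1108 kept it, 17 gained one, 81 lost one and 54 reversed. The cause was not tested for any of these moves unless stated.

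Pairing by the clone numbers of the labels gave 1791 genes at day 3, 1405 at day 7, 3207 over both days and 1 for the difference, against 106, 93, 883 and 0 without it, because the clone's own level leaves the error. As a random effect it gave 1815, 1392 and 3214. Array weights gave 409, 1402 and 2054, and 4847 for day 7 against day 3. Without trend day 3 had 58 and day 7 had 45. With no filter on low values they had 54 and 21, and day 7 against day 3 had 1104. With the mean over probe sets they had 59 and 55, and the marker lists 0. The arrays of that day alone gave 37 and 0, and 758 at day 7 with the block. Quantile normalization gave 48 at day 7, and array medians set equal gave 32. The erythroid score as a covariate, chosen after the data had been seen, gave 27 for day 7 against day 3 and 71 for the blocked difference.

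For lists an estimated correlation gave 0 at day 3, 1 at day 7, 0 over both days, 0 for the days and 0 for marker lists. With the block as well it gave 0, 0, 0 and 0. The test fry gave 7 at day 3, 5 at day 7 and 0 marker lists. Exact sign flips gave 0 at day 3 and 0 at day 7, where the smallest possible p exceeds the threshold.

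With each clone left out in turn, counts ranged from 1 to 129 at day 3 (21, 32, 2, 1, 43 and 57 without clones 1, 3, 4, 5, 7 and 8) and from 0 to 90 at day 7 (41, 48, 15, 0 and 0 without clones 1, 3, 5, 7 and 8). Over both days they ranged from 299 to 863 (573, 362, 299 and 381 without clones 1, 5, 7 and 8), and for day 7 against day 3 from 1 to 2143 (638, 452, 74 and 1 without the same clones). A clone of the other day acts through the shared spread. With the block the ranges were 861 to 1804 at day 3 (959, 1032 and 861 without clones 3, 4 and 5), 0 to 1574 at day 7 (0 and 300 without clones 7 and 8), 2415 to 3148 over both days and 0 to 113 for the difference (2 without clone 3, 113 without clone 6). Lists ranged from 11 to 12 at day 3, 9 to 10 at day 7, 12 to 13 over both days and 6 to 10 for the days.

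Reversed values were those of CFLAR, which had passed, of uncalled genes and lists, and of ribosomal proteins between the days, which had passed and were at -0.0164 with the test up after quantile normalization. A list counts as reversed where its mean or the direction of the test turned. With the replicate block these were naive and memory (0.18 at day 7, 0.18 over both days), early activation (-0.0899 and 0.0114) and, at day 7, apoptosis opposing (0.0551), the same with an estimated correlation. With the random effect it was apoptosis opposing (0.0551). With pseudocount 1 they were at day 7 cytokines and chemokines (-0.0263) and chemokine receptors and adhesion (0.00302). With pseudocount 64 they were costimulatory receptors (-0.0422 at day 7, -0.000944 over both days) and cytokines and chemokines (0.0242 at day 7). With no filter they were apoptosis promoting (0.0200 at day 7) and inhibitory receptors (-0.0455 over both days). The stricter filter reversed costimulatory receptors (-0.0505 at day 3, -0.12 at day 7, -0.0750 over both days) and cytokines and chemokines (0.0695 at day 7), and left some named genes without a value. Quantile normalization reversed naive and memory (0.19 at day 7) and early activation (-0.12 at day 7, -0.00507 over both days). Equal medians reversed cytokine receptors and STAT response (0.0439 at day 3), naive and memory (0.24 at day 7, 0.29 over both days), apoptosis opposing (0.13 at day 7) and inhibitory receptors (0.0482 over both days). The mean over probe sets reversed CFLAR (-0.0241) and BCL2L1 (-0.0139) over both days, and at day 7 costimulatory receptors (-0.0407), naive and memory (0.13) and cytokines and chemokines (0.0411). Array weights reversed MITF (-0.10), and fry cytokines and chemokines (0.0188 at day 7).

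Left-out clones reversed further values, given as ranges over the 8 clones. At day 7 these were naive and memory (0.12 to 0.26, reversed without clone 1, 2 or 3), cytokines and chemokines (-0.19 to 0.25, clones 2, 4, 6, 7 and 8), costimulatory receptors (-0.0668 to 0.10, clones 6 and 8), apoptosis opposing (0.0366 to 0.0767, clones 7 and 8), early activation (-0.17 to 0.0370, clone 7), 4-1BB and NF-kB response (-0.0702 to 0.25, clone 6) and apoptosis promoting (0.0465 to 0.11, clone 6). Over both days they were early activation (-0.0146 to 0.0621, clones 1 and 5), inhibitory receptors (-0.15 to -0.00659, clones 2, 4 and 5), MITF (-0.15 to 0.23, clone 3) and ELF3 (-0.0366 to 0.26, clone 3).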

Other observations

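IGHM, the heavy chain of IgM, rose from a mean signal of 24.6 to 301 at day 7 with eAPC:4-1BBL (2.97 ± 0.72, n = 3; blocked adjusted p = 0.00287), past the threshold in the blocked fit only, and the culture types differed by -0.17 ± 0.80 at day 3. The difference between the days did not pass (3.14; blocked adjusted p = 0.0615).

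The test of B cells was chosen after the result was seen, and the splits of arrays were chosen before. CCR7, EBI3 and FCER2, which B cells and lymphoblastoid lines also express, were higher with eAPC:4-1BBL in 8 of 8 clones, as the naming rule required. Against B cells as their source, the upper quartile of 19 other B cell markers was 0.16, while the smallest of the pattern's genes, FCER2, was at 1.91. Of those markers 11 of 19 were higher, none was held by another list, and their median signal was 25.4, with 134 as the highest. Low signal limits that test, and so does the choice of the pattern's genes from the largest increases. POU2AF1, a marker among the 19, was higher by 0.75 at day 3 and 0.77 at day 7. At day 7 alone the median of the 19 was 0.19, with members from IGHM (2.97) and JCHAIN (1.79) to BANK1 (-0.35) and CD79B (-0.41), which was not tested and leaves B cells at day 7 open.

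Of other splits of the same arrays, those that part every clone pair match the real one, and they were compared after the first results were seen. At day 3 there are 16 of these, too few to tell (106 genes, highest other 0). Among all splits 3 of 100 called at least 106, and the highest other called 831. That split set both arrays of clones 2 and 5 and the eAPC array of clone 1 against the rest, with mean erythroid scores of 8.96 and 6.53, which points to sample structure. The day 3 count also rests on single clones: it was 1 without clone 5, 2 without clone 4, 21 without clone 1, 32 without clone 3, 43 without clone 7 and 57 without clone 8. For genes over both days chance can be excluded (1 of 100 splits that part every pair; 883, highest other 29), also among all splits (1 of 100, highest other 321) and with the replicate block (1 of 100 sign patterns; 3207, highest other 493). The unblocked count of both days was 299 without clone 7, 362 without clone 5, 381 without clone 8 and 573 without clone 1. For day 7 against day 3 the real assignment called the most genes (1765), and 1 of 56 is the smallest share possible. The highest other called 641, with clones 1, 2 and 5 against the rest. Their arrays had erythroid scores of 7.15 to 9.53, against 5.01 to 7.37 in the other clones, which again points to sample structure. That share is under 0.05, but the real count was 27 with the erythroid score as a covariate. It was 1 without clone 8, 74 without clone 7, 452 without clone 5 and 638 without clone 1.

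For lists over both days, 4 of 100 splits that part every pair, the real one among them, called at least 12 lists (highest other 12). Among all splits 3 of 100 did (highest other 13), and the median of the others was 6 lists. Both shares are under 0.05, but other splits reached the real count, so chance is not excluded. These counts are from camera with the preset correlation: with an estimated correlation 0 of 21 lists passed (lowest adjusted p = 0.0991, and 0.192 with the block). At day 3 the 16 splits that part every pair are too few to tell (12 lists, highest other 11), and among all splits 4 of 100 called at least 12, the highest other 13. Chance cannot be excluded for day 7 against day 3 (17 of 56 for 8 lists, highest other 13) or for the marker lists of both days (61 of 100 for 1 list, highest other 4). Splits were too few to tell for genes at day 7 (2 of 10; 93, highest other 172), lists at day 7 (5 of 10; 9, highest other 10), genes at day 3 with the block (1 of 16; 1791, highest other 0) and genes at day 7 with the block (1 of 4; 1405, highest other 1).

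With the erythroid score as a covariate in the blocked fit of both days, chosen after the data had been seen, 3472 genes were called instead of 3207, and 3038 were called in both fits, all with the same sign.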
